A study of Arabidopsis thaliana with 39 samples.

How the data were processed

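Total RNA from the oscillation zone of the root tip was profiled on 39 Affymetrix ATH1 arrays, 1 biotin-labelled sample per array. The plants were Arabidopsis thaliana, ecotype Columbia, with the auxin reporter line DR5-GUS given as the source, 5 days old on standard media. The titles divide the arrays into OZ1 (20 arrays) and OZ2 (19 arrays). Per the labels' description OZ1 is the lower and OZ2 the upper part of the zone, while the tissue label states the opposite, so only the names OZ1 and OZ2 are used here. The submitters give each array a position from 1 to 39 that was used to find periodic expression. OZ1 takes positions 1 to 20 and OZ2 positions 21 to 39, and how the order was made is not stated in the sources used here. If the order came from these arrays, a periodic pattern along it is not independent evidence.

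The deposited values are intensity values, 1 per probe set and array, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. The trimmed mean between the 2nd and 98th percentile was 249.8 to 249.9 on the 39 arrays, so the values had been scaled per array before deposit. A scaling of this kind multiplies background together with signal, so an array with little labelled RNA has its dim probe sets raised. No further normalization between arrays was applied to the main values. The deposited instrument records (unit other, deposited by the authors with the arrays) gave the chip type and the scan day, and 3 scan days were found. Scan day 1 held 22 arrays (12 OZ1, 10 OZ2), scan day 2 held 8 arrays of OZ1, and scan day 3 held 9 arrays of OZ2. No pair of arrays held identical values, and the highest correlation between 2 arrays was 0.914.

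Of 22810 probe sets, 64 were Affymetrix controls and were left out of the tests. A probe set was tested if its mean log2 value over the 39 arrays was above the 40th percentile (log2 5.70, a signal of 51.8), which left 13627. The median signal per array was 54.4 to 164. No detection calls were used, and for arrays the number of arrays limits the precision. The probe table names 1 gene for 13513 probe sets and several for 503, and 8794 are unnamed here. By Entrez number 13436 of the 1-gene probe sets were matched to the reference annotation TAIR10.1, used only for names, locus identifiers and gene type. The array's genome build is not given in the sources used here, and no coordinates are printed. A gene with several probe sets was represented by the one with the highest mean, and 7526 genes had a tested one.

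Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) on log2 values, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. All tests were two-sided. OZ2 was set against OZ1 over 39 arrays. The order was tested with an F-test of 3 harmonics (6 terms) over the 39 positions, once alone and once with the region as an additional term, and within OZ1 and within OZ2 with a natural cubic spline of 3 degrees of freedom. The region and the order are confounded by construction, since each region holds consecutive positions.

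Before the data were examined, 23 gene lists were fixed, of which 10 had at least 3 tested members. A further 20 gene families were added after the probe table had been seen and before any list was tested. Lists were tested against the other genes with camera (preset correlation 0.01, and again with an estimated correlation) and, for the order, with Fisher's exact test and 100 orders, the deposited one and others permuted within the regions. Adjustment was over the fixed and over the added lists separately. The rule for named genes was also fixed: the 8 largest rises and 8 largest falls between regions, the 16 largest fitted ranges along the order, and the 2 members with the smallest adjusted p of each list with a called member. LBD16, ARF7, ARF19, IAA28, GATA23, CYCB1;1 and WOX5 were to be named whatever their result, and a further item of this rule is not reported here. LBD16 alone of those listed had a named probe set, and the others were not analysed here. The lists for auxin perception, root cap and cytosolic ribosomal proteins had no matched probe set, and those for cytokinin response and non-hair epidermis had no tested member.

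Alternatives planned before the data were examined were quantile normalization, log2(value + 16), no filter, a filter at the 60th percentile, array weights, robust eBayes, scan day as a block, 1, 2 or 4 harmonics, a von Neumann ratio, a linear trend, a spline with 4 degrees of freedom, the number in the title as a block, and the order as a term in the region fit. Added after seeing the data were the mean log2 signal of 18 hybridisation control probe sets as a term, fits without 6 arrays that lay nearer the other region, fits without 11 arrays whose hybridisation controls held over 5% of the signal, scan day 1 alone, and fits without each array in turn. The hybridisation controls are bacterial and phage transcripts added to every hybridisation mix, so after scaling their level is higher where the plant RNA gave less signal.

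The fits were tested on simulated arrays with the real means and spreads of the 13627 probe sets, 200 of them changed, 100 by a log2 size of 1 and 100 by 3. Of the changes between regions 26% of size 1 and 99% of size 3 were recovered. Along the order with the region as a term, with 2 cycles, 2% of range 1 and 67% of range 3 were recovered. Within OZ1 the shares were 1% and 22%, and within OZ2 0% and 22%. With the hybridisation control level as a further term the order fit recovered 0% of range 1 and 7% of range 3. The simulated patterns shared 1 phase, lowest near position 10, where the controls were fitted highest. That fit thus has little power to keep a true pattern of 2 cycles of this phase, and other phases were not simulated. Versions of the other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.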

Results

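The arrays profiled OZ1 and OZ2, adjoining parts of the oscillation zone, the stretch of the Arabidopsis root tip in which sites of later lateral roots are marked out. There were 20 arrays of OZ1 and 19 of OZ2. The series text speaks of 39 individual roots, while 14 of the 25 different numbers in the titles occur in both regions. Along the order these shared numbers follow the same sequence in both regions, except number 1, which is first in OZ1 and last in OZ2. This argues that a shared number stands for a common unit, though whether that unit is 1 root is not stated. The p-values of the main fits treat every array as independent, without a term for the shared numbers, and measure the spread between these arrays. The first comparison asked which transcripts differ between OZ1 and OZ2, and the second which transcripts vary with the submitters' order of the arrays.

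From OZ1 to OZ2, 2 of 3 root hair genes and 7 of 9 autophagy genes rose, all 7 of the latter in the ATG8 family. Of 4 histone H2B genes 3 fell, and of 7 tubulin genes 5 fell and TUA1 rose. As lists these passed with a preset correlation and not with an estimated one (adjusted p = 0.370, 0.191, 0.413 and 0.427 with an estimated correlation, in that order). EXPA18 and EXPA7, expansins of root hair cells, had log2 signals of 6.90 ± 2.27 and 7.82 ± 2.24 (SD, n = 20) in OZ1 and of 11.13 ± 1.75 and 11.25 ± 2.25 (SD, n = 19) in OZ2. The log2 difference of EXPA7 was 3.43 over all arrays and 2.09 on scan day 1 alone, and it did not pass with the scan day as a block (adjusted p = 0.096). MT1C, a metallothionein, was 33.0-fold higher in OZ2 (log2 difference 5.04 ± 0.78 SE, limma adjusted p = 5.19e-06). HTB4 and HTB2, which encode histone H2B, fell by 1.57 and 2.21 on the log2 scale from OZ1 to OZ2. HTB4 passed with the scan day as a block (adjusted p = 0.0474) and HTB2 did not (adjusted p = 0.214), and on scan day 1 alone the log2 difference of HTB2 was -0.98. In all, 3949 of 13627 probe sets (29.0%) passed the test, 1819 higher and 2130 lower in OZ2, and 2814 of them differed by at least 2-fold. They included 2161 named genes, 962 higher and 1199 lower. The median log2 difference over all tested probe sets was -0.0949.

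**Figure D1:**
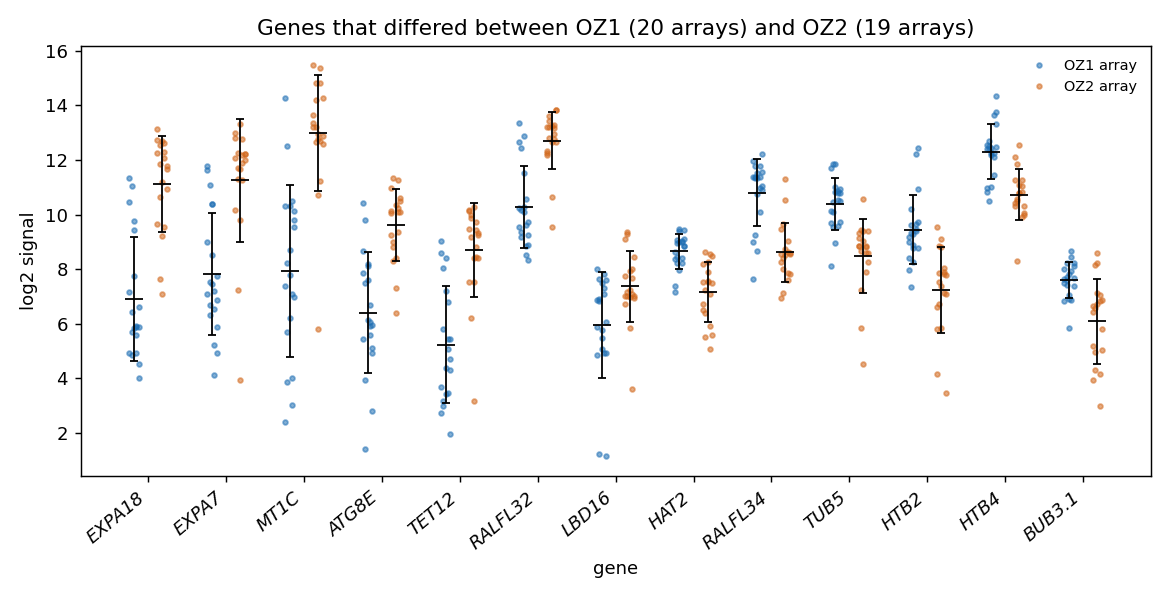
Log2 signal (vertical axis) of 13 genes (horizontal axis) in each OZ1 array (blue) and OZ2 array (orange), with the mean and SD of 20 and 19 arrays in black. EXPA18 had a mean of 6.90 in OZ1 and 11.13 in OZ2, and HTB2 one of 9.44 in OZ1 and 7.23 in OZ2; single arrays of the regions overlap for every gene drawn.

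The largest rises in OZ2 were those of AT3G18170 (log2 difference 5.47 ± 0.68 SE, limma adjusted p = 2.89e-07), AT4G13580 (5.16 ± 0.71), AT5G66390 (5.07 ± 0.73), AT4G02090 (5.07 ± 0.77), MT1C, AT2G21100 (4.98 ± 0.68), AT3G53980 (4.78 ± 0.70) and AT3G18280 (4.76 ± 0.75). The largest falls were those of AT5G62340 (-4.27 ± 0.76), AT5G51490 (-4.16 ± 0.59), AT1G73620 (-3.84 ± 0.75), AT5G62330 (-3.72 ± 0.55), AT5G50740 (-3.63 ± 0.59), AT3G50900 (-3.49 ± 0.54), AT5G12940 (-3.39 ± 0.53) and AT1G54890 (-3.28 ± 0.44). The OZ1 means of AT3G18170 (4.58), AT5G66390 (5.31), AT4G02090 (4.58) and AT3G53980 (4.38) lay below the filter level of 5.70. So did the OZ2 means of AT5G62340 (5.54), AT5G51490 (4.32) and AT5G62330 (4.17), while the lower means of the other genes in this paragraph lay above it. For the genes below that level the size of the difference is uncertain. With the scan day as a block AT5G62340 no longer passed (adjusted p = 0.0821), and on scan day 1 alone its log2 difference was -2.46. On that day OZ1-2, OZ1-6 and OZ1-10, which lay nearer OZ2, had log2 signals of 3.93, 7.25 and 3.28 for this gene. OZ2-32 and OZ2-38, which lay nearer OZ1, had 9.29 and 11.63.

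Among the lists fixed beforehand, root hair genes stood above the other genes (camera adjusted p = 0.0119; adjusted p = 0.370 with an estimated correlation). This list, the only fixed one called, did not pass with the scan day as a block (camera adjusted p = 0.169). EXPA7 and EXPA18 of its 3 tested members rose in OZ2, and SCN1 had a log2 difference of 0.32. With the scan day as a block EXPA18 passed (adjusted p = 0.0026). Of 3 mitosis genes, BUB3.1, a spindle checkpoint protein, and AUR1, an aurora kinase, fell by 1.51 and 0.93 on the log2 scale (camera adjusted p = 0.261). Of 3 genes of DNA replication and its histones, HTB1 and PRL, a subunit of the replicative helicase, fell by 1.26 and 0.82 (camera adjusted p = 0.143). None of these 4 cell cycle genes passed with the scan day as a block, where BUB3.1 had a log2 difference of -1.31 (adjusted p = 0.0878), AUR1 one of -0.81 (0.285), HTB1 one of -1.05 (0.0827) and PRL one of -0.60 (0.32).

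HAT2 and GH3.17, an auxin-induced transcription factor and an auxin-conjugating enzyme, fell by 1.48 and 1.66 on the log2 scale in OZ2, and the other 3 of the 5 auxin response genes did not pass (camera adjusted p = 0.375). Of 4 genes of lateral root founder cells, RALFL34, a signalling peptide, fell by 2.19, AUR1, also on the mitosis list, fell, and LBD16, a transcription factor of lateral root initiation, rose by 1.44 ± 0.50 SE (adjusted p = 0.0268). LBD16 did not pass with the scan day as a block (log2 difference 1.35, adjusted p = 0.206) or with the level of the hybridisation controls as a term (1.07, adjusted p = 0.0628). The list as a whole did not stand apart (camera adjusted p = 0.376). Of 11 genes of cell wall expansion 4 rose and 2 fell, with XTH32 up by 2.82 and XTH20 by 1.69 (camera adjusted p = 0.376), and under the scan day block 1 rose and 2 fell. Of 6 photosynthesis genes, the list for shoot tissue, 4 rose, among them LHCB4.1 by 1.95 and PSBY by 1.12 (camera adjusted p = 0.081). The photosynthesis list passed with the scan day as a block (camera adjusted p = 0.0338) with 1 called member, and did not with an estimated correlation (adjusted p = 0.405). With the control level as a term 2 of its members rose (camera adjusted p = 0.146). Under the block LHCB4.1 (adjusted p = 0.0659) and PSBY (0.107) did not pass. WRKY53 and STZ, 2 of the 3 touch and wounding genes, rose by 1.11 and 1.22 (camera adjusted p = 0.224). No member of the xylem list (3 tested, camera adjusted p = 0.571) or of the heat shock list (4 tested, camera adjusted p = 0.571) passed. Lists with 1 or 2 tested members were not tested as lists. AGL16, 1 of 2 MADS-box genes, rose by 0.65, and COR47, a dehydrin and the tested member of the gibberellin and abscisic acid list, rose by 2.27. None of WRKY53 (log2 difference 0.96, adjusted p = 0.242), STZ (1.22, 0.205), XTH20 (1.18, 0.157), AGL16 (0.67, 0.144) and COR47 (1.54, 0.133) passed with the scan day as a block, and STZ did not with the control level as a term (1.08, adjusted p = 0.0748). No tested member passed in the lists for auxin transport (1 tested), endodermis (1), phloem (2), quiescent centre (2), circadian clock (1) and ethylene and brassinosteroid response (2). The counts adjusted over the list alone were 2 of 3 for root hair, 2 of 5 for auxin response, 3 of 4 for founder cells, 2 of 3 for mitosis, 2 of 3 for replication, 7 of 11 for cell wall expansion, 4 of 6 for photosynthesis, 2 of 3 for touch, and 0 for xylem and for heat shock.

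Of the 20 added families, 5 stood apart with the preset correlation, and 0 with an estimated one. Of 9 autophagy genes 7 rose, with ATG8E, a ubiquitin-like protein of the autophagosome, 9.18-fold higher over all arrays (log2 difference 2.35 on scan day 1 alone), and ATG8F 3.26-fold higher (1.32 on scan day 1 alone; camera adjusted p = 6.0e-05; adjusted p = 0.191 with an estimated correlation). All 7 belong to the ATG8 family, while ATG8G of this family and ATG3 (log2 difference 0.02) did not pass. Of 4 histone H2B genes 3 fell (camera adjusted p = 0.0174; adjusted p = 0.413 with an estimated correlation). Of 7 tubulin genes 5 fell and 1 rose, with log2 differences of -1.91 for TUB5 and -1.37 for TUB6 (camera adjusted p = 0.0248; adjusted p = 0.427 with an estimated correlation). Of 8 tetraspanins 5 rose, among them TET12 by 3.47 and TET6 by 1.33, and 1 fell (camera adjusted p = 0.0277; adjusted p = 0.191 with an estimated correlation). Of 21 expansins and xyloglucan endotransglucosylases 10 rose and 3 fell (camera adjusted p = 0.0425; adjusted p = 0.413 with an estimated correlation). Among these families, with the scan day as a block, the autophagy genes (camera adjusted p = 0.00312, 3 members called) and the tubulins (0.00239, 5 falling, with TUA1 no longer passing at an adjusted p of 0.291) passed, and histone H2B (0.136, 1 called), tetraspanins (0.136, 2 rising and 1 falling) and the expansin family (0.733, 3 rising and 3 falling) did not. Neither the autophagy genes nor the tubulins passed under the block with an estimated correlation (camera adjusted p = 0.389 for each). Without the 6 arrays that lay nearer the other region the tubulins did not pass (0.0682). With the title's number as a fixed block, over the shared numbers, the tetraspanins and the expansin family did not pass (camera adjusted p = 0.0776 for each), and the other families named here did. With the control level as a term TUA1 also lost its call.

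In the other families, 2 of 9 endoglucanases rose and 3 fell, 5 of 18 wall acetylation genes rose and 3 fell, 3 of 7 RALF-like peptides rose and 1 fell, 3 of 18 serine carboxypeptidase-like genes rose and 1 fell, and 3 of 12 beta-glucosidase and ER body genes rose and 3 fell. Of 24 UDP-glycosyltransferases 5 rose and 2 fell, of 21 ubiquitin-conjugating and deubiquitinating enzymes 2 rose and 4 fell, of 8 tau-class glutathione transferases 1 rose, and of 6 LSM proteins 1, of 11 RNA polymerase subunits 2 and of 69 plastid-encoded genes 2 fell. Under the scan day block the counts of rising and falling genes were 0 and 2 for endoglucanases, 3 and 2 for wall acetylation, 1 and 1 for RALF-like peptides, 1 and 1 for serine carboxypeptidase-like genes, 2 and 2 for beta-glucosidases and ER bodies, 2 and 0 for UDP-glycosyltransferases and 1 and 0 for the ubiquitin enzymes, and 0 for the glutathione transferases, LSM proteins, RNA polymerase subunits and plastid-encoded genes. GH9C1, an endoglucanase, rose by 3.13 and GH9B7 had a log2 difference of -0.89. TBL41 and TBL38 rose by 2.77 and 2.78, RALFL32 by 2.44, scpl48 by 2.44, SCPL45 by 1.02, BGLU46 by 2.54, UGT73D1 by 2.72, UGT87A2 by 1.76, UBC29 by 1.71, UBC22 by 0.73 and GSTU28 by 1.68. NAI2, a component of endoplasmic reticulum bodies, had a log2 difference of -1.32, LSM6A one of -1.22, NRPB9B one of -0.96 and NRPB6B one of -0.96. The plastid-encoded psaI and ycf4 had log2 differences of -1.04 and -0.98. With the control level as a term 9 plastid-encoded genes fell and their list passed (camera adjusted p = 0.00079), and it did not with an estimated correlation (adjusted p = 0.668). With the scan day as a block GH9C1 (adjusted p = 0.107), TBL38 (0.0543), SCPL45 (0.23), UBC22 (0.124), GSTU28 (0.517), LSM6A (0.109), NRPB9B (0.146), NRPB6B (0.213), psaI (0.706) and ycf4 (0.453) did not pass. On scan day 1 alone the log2 difference was 1.78 for GH9C1, 0.60 for GSTU28, 0.57 for SCPL45, -0.34 for psaI and -0.65 for ycf4. Of the remaining families, no member of the ESCRT, exocyst, mitochondrion-encoded and SWEET lists passed, and the smallest camera adjusted p among the families that did not stand apart was 0.119, for plastid-encoded genes.

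Scan day 1 is the single day with arrays of both regions, so the block gives the differences within its 22 arrays. Among them were OZ1-2, OZ1-6, OZ1-10, OZ2-32 and OZ2-38, which lay nearer the other region. A smaller difference or a lost call under the block therefore does not by itself point to the scan day. This applies to each gene and list set against the block above. Of the 61 genes named by the fixed rules 25 lost their call with the block; 17 of these had a log2 difference within 1.5 times of that over all arrays and 8 moved by more. With the scan day as a block 1535 probe sets passed, and 801 passed in the 22 arrays of scan day 1 alone, 315 higher and 486 lower in OZ2. The differences within scan day 1 and between the arrays of the other days correlated at r = 0.641 across probe sets, which are not independent replicates.

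Single arrays did not all lie with their region. On an axis from the OZ1 mean (0) to the OZ2 mean (1), both taken over the other arrays, the median was -0.114 in OZ1 and 0.982 in OZ2. OZ1-10 lay at 1.09, OZ1-2 at 0.838, OZ1-6 at 0.748 and OZ1-3 at 0.724, and OZ2-38 lay at -0.347 and OZ2-32 at 0.288. These 6 arrays also correlated better with the arrays of the other region. The first principal component held 25.8% of the variance.

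**Figure D2:**
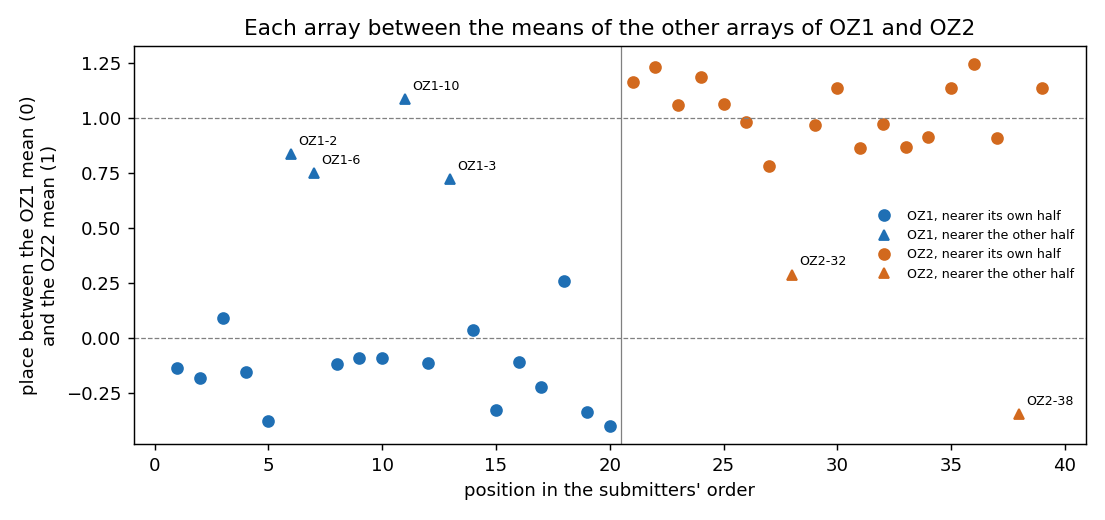
Place of each array (vertical axis, 0 at the mean of the other OZ1 arrays and 1 at the mean of the other OZ2 arrays, no unit) against its position in the order (horizontal axis). Triangles mark the 6 arrays that lay nearer the other region, with OZ1-10 highest in OZ1 at 1.09 and OZ2-38 lowest in OZ2 at -0.347.

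Along the order, beyond the step between the regions, the called genes included plastid-encoded ones, pseudogenes and transposable elements. With the region as a term 56 probe sets passed, 29 of them named genes. The smallest adjusted p was shared by an unnamed probe set and ndhK, a plastid gene for an NADH dehydrogenase-like subunit, with a fitted range of 3.83 on the log2 scale and its highest fitted value at position 10 (limma adjusted p = 0.0027). Of the 69 tested plastid-encoded genes 4 passed, ndhK, psbN, ycf3 and psbD (Fisher's exact test, adjusted p = 0.00259). The last 2 are named because they complete that count. Fisher's test takes genes as independent. The permuted orders counted instead the members with an unadjusted p under 0.05, 36 of the 69 (adjusted p = 0.167 from permuted orders). Of the 29 named genes 8 are annotated as pseudogenes or transposable elements, as are 116 of the 7526 tested. Of the 56, 46 had their largest amplitude at 2 cycles over the 39 positions, 8 at 1 and 2 at 3. The region term takes up part of any 1-cycle pattern. The shared numbers also run in the same sequence in each region, so anything that follows that sequence appears as 2 cycles. These counts therefore do not show a period. The fitted ranges went from 1.56 to 6.93, with a median of 3.85.

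Among the named genes that passed, the 16 with the largest ranges were AT2G39160 (fitted range 5.94, adjusted p = 0.0229), AT5G45880 (5.91), AT3G30510 (5.43), AT2G33350 (5.20), AT3G33066 (5.00), AT3G31360 (4.84), AT1G40150 (4.77), AT4G03790 (4.48), AT5G53740 (4.28), AT1G57830 (4.28), psbN (4.22), AT2G01840 (4.21), AT5G66520 (4.16), AT4G36550 (4.12), AT5G32430 (4.12) and AT2G07722 (3.99). LBD16 had a fitted range of 5.44, and its order pattern did not pass over all tested probe sets (limma adjusted p = 0.134). No list fixed beforehand held a called member, and 0 of the 10 stood apart by Fisher's exact test or by permuted orders. Adjusted over the list alone, 1 member passed in each of the founder cell, xylem and photosynthesis lists. In the founder cell list this was LBD16 (unadjusted limma p = 0.00377, and 0.357 with the control level as a term).

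The hybridisation controls, which measure no plant transcript, varied along the order. Beyond the region the 3 harmonics held 74.8% of the variance of their mean, with F = 15.3 (permutation test of the order within regions, p = 1e-05, the smallest 100000 permutations can give). Taken singly, the 18 control probe sets had F between 9.98 and 15.2 (median 13.1). Of these, 13 lay above the highest F of a tested probe set, 11.2. That is limma's moderated F, while the 15.3 of the controls' mean is an ordinary F, so the comparison is rough. The fitted range of the controls was 3.62 on the log2 scale, highest at position 10 and lowest at position 22. Of the 56 order calls 43 correlated above 0 with them within regions and 13 below 0. With their level as a term 0 probe sets passed in limma (372 at an unadjusted p under 0.05). With quantile normalization 0 passed (1427 unadjusted), against 1854 unadjusted in the fit as planned. By chance 681 would be expected at that unadjusted threshold.

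**Figure D3:**
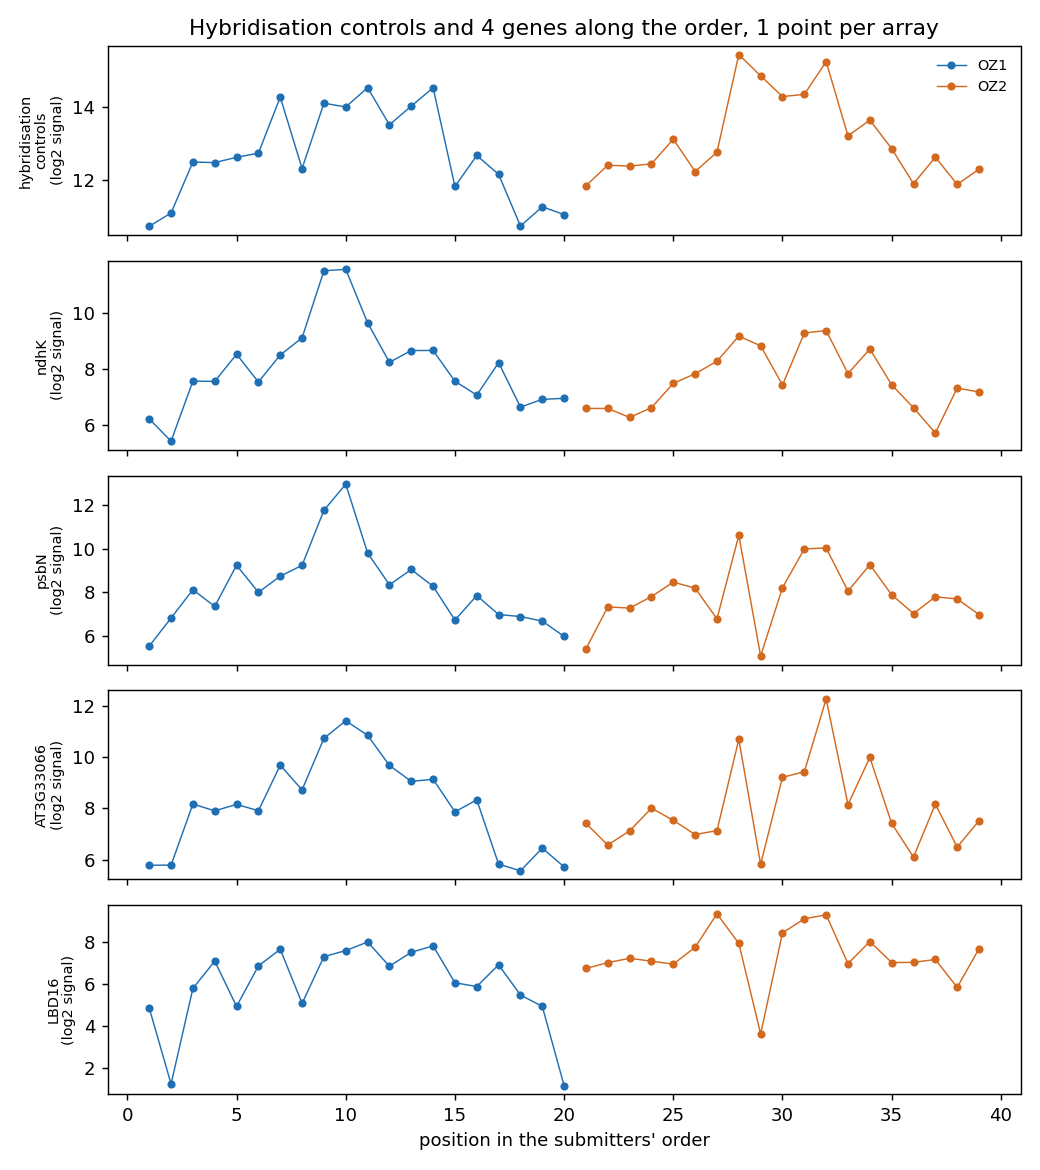
Log2 signal (vertical axes) of the 18 hybridisation controls (mean) and of ndhK, psbN, AT3G33066 and LBD16 in each array against its position in the order (horizontal axis), OZ1 in blue and OZ2 in orange. The fitted curve of the controls is highest at position 10, as are those of ndhK, psbN and AT3G33066. LBD16 did not pass the test of the order adjusted over all tested probe sets.

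Without the region as a term 2206 probe sets followed the order, of which 1627 also differed between the regions. With the scan day as a block there were 1069. Within OZ1 20 probe sets varied along the order, among them ndhK, psbN and AT3G33066, and 6 of 100 orders gave as many. Within OZ2 0 passed in limma (771 at an unadjusted p under 0.05, where 681 would be expected by chance), so none passed in both regions. The shape of the curve over the relative position in the region differed between OZ1 and OZ2 for 0 probe sets in limma (364 at an unadjusted p under 0.05). A curve over the relative position common to both regions passed for 268 probe sets (2331 at an unadjusted p under 0.05).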

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

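The tests of scan day and of permuted orders on the order calls beyond the region were chosen after the results were seen. So were the tests of calls on single scan days, of swapped arrays and of OZ2-38. The fits with the control level, without the 6 arrays and on scan day 1 were also chosen then.

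The hybridisation controls stood out as a signal outside the plant measurements: their fitted range along the order was 3.62 on the log2 scale. The order calls beyond the region moved with them. After the order had been taken out of both, 55 of the 56 called probe sets still changed with the control level in the direction of their order pattern. That is 98.2% (exact 95% interval 90.45 to 99.95, too narrow since the probe sets share their arrays and are not independent), against 74.5% of all tested probe sets. This is consistent with the amount of labelled RNA as a source of the order calls, through the scaling of each array. The loss of all 56 calls with the control level as a term (0 left) weighs less, since that fit recovered 7% of simulated patterns of range 3. Those patterns shared 1 phase, lowest near where the controls were fitted highest, and other phases were not simulated. The scan day as the cause is argued against by the 84 calls with it as a block, though in the 22 arrays of scan day 1 alone 0 passed (2089 at an unadjusted p under 0.05). Of 100 orders 1 gave as many calls, the deposited one (56 against at most 1 in another order). That argues against chance only if the order was made without these arrays. The permutations also shuffled each region separately, which breaks the sequence of shared numbers common to both. A biological oscillation with which the RNA yield moves stays open and was not tested, as does an order derived from these arrays.

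Arrays OZ1-2, OZ1-3, OZ1-6, OZ1-10, OZ2-32 and OZ2-38 lay nearer the other region. A swap of the 2 arrays of a number is argued against for numbers 6, 10 and 32, where 0 of the partner arrays lay nearer the other region. For numbers 2, 3 and 38, 0 had a partner array here, so a swap cannot be told apart from other causes. Low labelled RNA is argued against for OZ2-38, whose controls held 1.69% of the signal, below the OZ2 median of 2.67%. In OZ2-32 they held 17.3%, the highest share of the 39 arrays, and in OZ1-10 10.5%, OZ1-6 8.88%, OZ1-3 5.82% and OZ1-2 3.18%, above the OZ1 median of 2.38%. OZ1-31 with 9.55%, OZ1-15 with 5.95%, OZ1-16 with 5.49%, OZ2-9 with 14.8% and OZ2-22 with 12.3% lay with their own region, so the share does not tell whether low labelled RNA moved these 5. A single wrong label, a dissection at another place or a true difference between roots stay open, untested.

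The region calls were set against 3 technical explanations. Chance is excluded, since 1 of 100 splits of the arrays gave as many (3949 against at most 1 in another split). The amount of labelled RNA is argued against, since 89.7% of the calls remained with the control level as a term. The scan day cannot have made the 801 calls within scan day 1, but how much it adds to the others cannot be told apart. Of 3670 probe sets called on scan days 2 and 3 alone, 88.0% kept their direction on scan day 1. That share lies between the bounds set of 60% and 90%. Scan day 1 also held OZ1-2, OZ1-6, OZ1-10, OZ2-32 and OZ2-38, which lay nearer the other region. A direction lost there thus need not come from the scan day, and scan day 1 without these arrays was not fitted. The planned share, 99.9% of all calls with the same direction on scan day 1, decides nothing, because those arrays were part of the fit that made the calls.

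For the order over all arrays 1 of 100 orders gave as many calls (2206 against at most 4). Those permutations also mix the regions, so the count does not separate the order from the difference between OZ1 and OZ2. For OZ1 6 of 100 orders gave as many as the 20 calls, so chance is not excluded; the highest other order gave 163, which points to a structure among the arrays whose source was not tested. For OZ2, with 0 calls, all 100 orders give as many by construction (up to 129), so the permutations decide nothing there.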

How the results depend on the processing

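Fits with the control level, without the 6 arrays nearer the other region, without arrays over 5% control signal, on scan day 1 alone, without each array in turn, and of the lists with scan day as a block were chosen after seeing the data; the others were planned, and all planned ones were run. The cause was not tested unless stated. The region count of 3949 lay between 3389 and 5614 under 10 other settings, but was 6342 with array weights, 1535 with scan day as a block, 801 on scan day 1 alone (fewer arrays) and 0 with 3 harmonics of the order as a term (1216 unadjusted), which are confounded with the region. The rise to 5614 without the 6 arrays follows from how they were picked. The count over all arrays (2206) was 3589 with no filter, 4495 with array weights, 1069 with scan day as a block, 808 with the control level and 4210 without the 6 arrays. The order count with the region as a term (56) was 0 with quantile normalization, 113 with log2(value + 16), 503 with no filter, 36 at the 60th percentile, 373 with array weights, 0 with the control level, 0, 305 and 30 with 1, 2 and 4 harmonics, 0 without arrays over 5% control signal, 0 on scan day 1 alone and 0 by the von Neumann ratio (1276 unadjusted). Within OZ1 (20) it was 2 with quantile normalization, 11 with log2(value + 16), 13 at the 60th percentile, 1236 with array weights, 0 with the control level, 37 without the 4 OZ1 arrays and 0 with a linear trend. Within OZ2 (0) it was 1 with array weights. Of 61 named region genes (53 of them tested at the 60th percentile) none changed direction where it was tested under the settings named above, leaving out single arrays aside, all 61 lost their call with the 3 harmonics as a term, 35 on scan day 1 alone, 25 with scan day as a block, and at most 5 under each other one. No detection calls were used, so how far dim probe sets lie above background is open.

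Leaving out each array in turn gave 3643 to 4406 region calls, 1805 to 2569 over all arrays, 15 to 119 with the region as a term, 5 to 23 within OZ1 and 0 to 0 within OZ2. The count with the region as a term was 15 without OZ1-1, 31 without OZ1-4, 32 without OZ1-9, 34 without OZ1-10, 119 without OZ1-13, 31 without OZ1-15, 22 without OZ1-16, 35 without OZ1-33, 28 without OZ2-4, 97 without OZ2-15 and 28 without OZ2-19. Within OZ1 it was 5 without OZ1-1, 6 without OZ1-15, 7 without OZ1-4, 8 without OZ1-16 or OZ1-20, 10 without OZ1-10 or OZ1-32, 11 without OZ1-31, 12 without OZ1-3 and 13 without OZ1-14, OZ1-19, OZ1-23 or OZ1-33.

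With the title's number as a replicate block the region count was 3601 (fixed, shared numbers) and 4064 (random), the order counts 55 with and 2282 without the region as a term, and 2 fixed lists passed by region (root hair and photosynthesis) in place of 1. The 14 pairs' deviations correlated at -0.25 to 0.20, 3 above 0.1, and 2 correlated best with their own number. Shared numbers thus held little common variation, and the main fits did not take them as pairs. This does not show that they come from different roots. Of the fixed lists 0 passed with an estimated correlation and 3 without the 6 arrays (root hair, photosynthesis and replication); with scan day as a block 1 passed, photosynthesis in place of root hair, and 0 with an estimated correlation. With the control level as a term 1 passed, and 0 with an estimated correlation.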

Other observations

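The test of the direction of the regions was chosen after the results were seen.

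The labels disagree on whether OZ1 or OZ2 lies nearer the shoot. A hypothesis from the gene lists is that OZ2 may be the part nearer the shoot, where root hair genes would be higher and cell division genes lower. Of the 9 tested members of the root hair, mitosis and replication lists, 6 were called in that direction (EXPA7, EXPA18, BUB3.1, AUR1, HTB1 and PRL) and 0 in the other. The lists were fixed before the data were examined, but the choice of these 3 lists and the bound of more than 1 in 2 members were set with these counts already known, so the count describes the data the hypothesis came from and does not test it independently. With the scan day as a block 1 of the 9 passed, EXPA18.

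Plastid-encoded transcripts moved with the hybridisation controls: 68 of the 69 tested correlated above 0 with the control level within regions, with a median r of 0.42, as did 13 of 13 mitochondrion-encoded ones, with a median r of 0.32 (across genes, which are not independent replicates). Over all tested probe sets 51.2% correlated above 0, with a median r of 0.011.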
